A study of Mus musculus with 24 samples.

How the data were processed

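Cerebral cortex RNA was sequenced from 24 individual mice. One line carried a truncated human FUS (residues 1 to 359, called the FUS line here), and the other carried human TARDBP with the A315T substitution, which encodes TDP-43, under the Prnp promoter (the TDP line). Both lines were on a C57BL/6 background. The FUS line comprised 7 mutants and 5 wild-type littermates taken at postnatal days 49 to 51, and the TDP line comprised 6 mutants and 6 wild-type littermates taken at postnatal days 57 to 62.

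Per the labels, RNA was extracted with TRIzol and mRNA libraries were read as 51-base single-end reads on a HiSeq 4000. The authors removed adapters and low-quality reads, mapped the rest to the mouse genome (mm10) with STAR 2.6 and counted reads per gene with HTSeq; SAMtools is also named. The deposited table holds counts, as whole numbers per Ensembl gene and mouse, without normalization. Neither the strand setting of the counting nor the annotation release is given, so genes that overlap another gene, or share near-identical sequence with one, are reported as uncertain in origin.

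The table held 55573 genes, of which 39893 had at least 1 count, and 55394 identifiers were matched to names in the GENCODE M21 annotation (GRCm38). The other 179 were kept under their identifiers, and 99.98% of counts fell on matched genes. No library was a copy of another of its group: the smallest chi-square per degree of freedom between replicates was 3.45. Libraries of different groups were not compared in this way. Total counts ran from 10205864 to 29954072 per library. Sex was read from Y-linked genes and Xist, since the labels do not give it: 20 mice were male, and 4 of the FUS line, 2 of each genotype, were female.

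Each line was fitted on its own with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with genotype as the only term. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fit of all 24 libraries tested the difference of the mutant effects (FUS minus TDP). Fold changes are those of the edgeR fit, mutant against wild type, with the standard error (SE) on the log2 scale. Levels are CPM, counts scaled to a fixed library size, as mean ± SD over mice. For genes with 0 counts in a group, the fold was bounded with a floor of 3 counts over the group; such bounds and the 95% counting intervals cover counting error only, because PCR copies of a molecule are not told apart.

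Effects of the lines were also compared as Pearson's r across genes of the differences of mean log2 CPM (prior count 2), with exact permutation of the genotype labels within a line, and as the overlap of genes past threshold with Fisher's exact test. Genes are not independent replicates, so the permutations moved mice and not genes.

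Before the data were examined, 42 gene lists (795 entries, all found in the annotation) were fixed. They covered transgene and promoter genes, cortical and neighbouring-tissue cell types, RNA-binding and disease genes, stress, immune, synaptic, cytoskeletal, mitochondrial, ribosomal and housekeeping programs. Each was tested with camera of limma 3.58.1, with the preset correlation of 0.01 and again with a correlation estimated per list, and adjusted over the 42 lists. Counts of list members cover only the genes that passed the filter. Mean log2 CPM per list and mouse was also compared by exact permutation of genotype within the line. The rule for naming genes was fixed at the same time. It took Fus, Tardbp, Prnp and Thy1, then up to 10 genes per direction with the largest change among those past threshold, with a mean of at least 1 CPM and an established symbol. It then took up to 4 genes past threshold per list, or the 1 with the lowest p where none passed, and up to 6 genes per direction for the difference of effects. Predicted gene models are named outside this rule, chosen after their values were seen.

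Alternatives fixed beforehand were RLE scaling, no filter on low counts, a filter of mean CPM of at least 1, DESeq2 1.42.0, a fit of all 24 libraries for each line, a replicate block, the mean of the Y-linked genes as a covariate, prior counts of 0.5 and 5, a list correlation estimated from the data, and leaving out each library in turn. Males alone, an adjusted p under 0.1 for the gene counts, and the striatal list score as a covariate were chosen after seeing the data, as was leaving Aldoc out of the astrocyte list. Replicate numbers were read as labels of separate mice: the mutant and wild type of a number were most alike in 2 of 5 pairs in the FUS line and 2 of 6 in the TDP line, and their correlations exceeded 0.1 in 3 and 5 of these pairs. Such a check compares mice of the same number only, so it could not show a grouping that several numbers share. Genotype labels were also reassigned within each line in 100 splits per comparison. Transcripts of genes past threshold were aligned with BLAST+ 2.17.0+ to all annotated transcripts, and matches of at least 95% identity over at least 51 bases counted as near-identical.

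The fits were tested on simulated data with the group sizes and the per-gene spread of these libraries. Genes were drawn independently, without the variation that genes share between mice. Changes were planted in genes with a mean of at least 1 CPM. A planted 1.5-fold change was called for 65.3% of genes in the FUS design, 74.7% in the TDP design and 55.3% for the difference of effects. For a 1.25-fold change these shares were 21.3%, 37.3% and 10.7%. Human transgene sequence was not analysed here, since the deposited counts are per mouse gene.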

Results

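Gene expression in the cerebral cortex was measured by RNA sequencing as read counts per gene in 24 mice. The FUS line gave 7 mutant and 5 wild-type libraries, with 16658608 to 29954072 and 11055231 to 27057563 counts each. The TDP line gave 6 mutant and 6 wild-type libraries, with 10205864 to 21351032 and 15076870 to 24864033 counts each. Between 25836 and 29692 genes had a count in a library. Expression of striatal genes, a tissue next to the cortex, differed 7.78-fold between the lowest and the highest of the 24 mice, and their list score (mean log2 CPM) was 3.63 ± 1.26 (SD, n = 7) in FUS mutants, 3.77 ± 1.11 (n = 5) in their wild types, 3.10 ± 1.05 (n = 6) in TDP mutants and 4.24 ± 1.06 (n = 6) in theirs.

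The comparison of FUS mutants with wild-type littermates asked which cortical genes differed with the truncated human FUS. Counts on Fus and Thy1 rose, together with those on 4 processed pseudogenes. Fus (ENSMUSG00000030795, chromosome 7, 127967457 to 127985701), which encodes an RNA-binding protein of the nucleus, was 374 ± 53.9 CPM (SD, n = 7) in mutants and 233 ± 17.0 CPM (n = 5) in wild types, a 1.60-fold rise (log2 0.68, SE 0.09, edgeR adjusted p = 0.0107). Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), a neuronal surface protein whose promoter is often used to drive transgenes in neurons, was 1902 ± 361 CPM (n = 7) in mutants and 673 ± 69.4 CPM (n = 5) in wild types, a 2.83-fold rise (SE 0.13 on the log2 scale, edgeR adjusted p = 3.77e-05). For both genes, 7 of 7 mutants lay above every wild type. Fus overlaps a predicted gene and shares near-identical stretches with 6 other genes, so reads counted on it are uncertain in origin.

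The 4 pseudogenes were chosen after their values were seen. Gm10167 (ENSMUSG00000066554, chromosome 5, 148182899 to 148184377) was 286 ± 75.2 CPM (SD, n = 7) in mutants and 22.9 ± 2.39 CPM (n = 5) in wild types, 12.5-fold higher (edgeR adjusted p = 1.01e-07). Gm7199 (ENSMUSG00000080778, chromosome X, 163477652 to 163479136) was 47.0 ± 13.7 CPM against 2.62 ± 0.681 CPM (n = 7 and 5), higher by log2 4.17 (edgeR adjusted p = 2.51e-07). Gm8309 (ENSMUSG00000108786, chromosome 7, 95461991 to 95463438) was 38.8 ± 12.6 CPM against 0.308 ± 0.305 CPM, and Gm47721 (ENSMUSG00000113130, chromosome 13, 20645757 to 20647164) was 0.973 ± 0.210 CPM against 0.0637 ± 0.0801 CPM (edgeR adjusted p = 2.51e-07 and 0.00141). All 4 aligned to Fus transcripts, at 92.1% identity over 1558 bases for Gm10167, 86.3% over 1570 for Gm7199, 89.1% over 1492 for Gm8309 and 73.9% over 748 for Gm47721. Gm47721 also aligned at 80.6% over 196 bases. Gm10167 overlaps Mtus2, and Gm10167 and Gm7199 share near-identical stretches with Fus, so the gene of origin of their reads is uncertain. The identity of these reads with mouse or human FUS sequence was not analysed here.

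Tardbp (ENSMUSG00000041459), which encodes TDP-43, was 155 ± 4.85 CPM (SD, n = 7) in FUS mutants and 157 ± 9.65 CPM (n = 5) in wild types, and Prnp (ENSMUSG00000079037), the prion protein gene, was 709 ± 23.8 and 697 ± 70.6 CPM (edgeR adjusted p = 0.949 and 0.967). Of 18098 genes tested with edgeR, 6 passed, all 6 higher in mutants. An unadjusted p under 0.05 was found for 1055 genes, 428 higher and 627 lower, where chance gives 904.9. DESeq2 called 19 genes, 13 higher and 6 lower. The call on Fus was lost among males alone (log2 0.62, edgeR adjusted p = 0.0662) and without wild type 2 (log2 0.68) or wild type 3 (log2 0.65). With a replicate block Fus (edgeR adjusted p = 0.135) and Gm47721 (edgeR adjusted p = 0.124) did not pass.

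**Figure D1:**
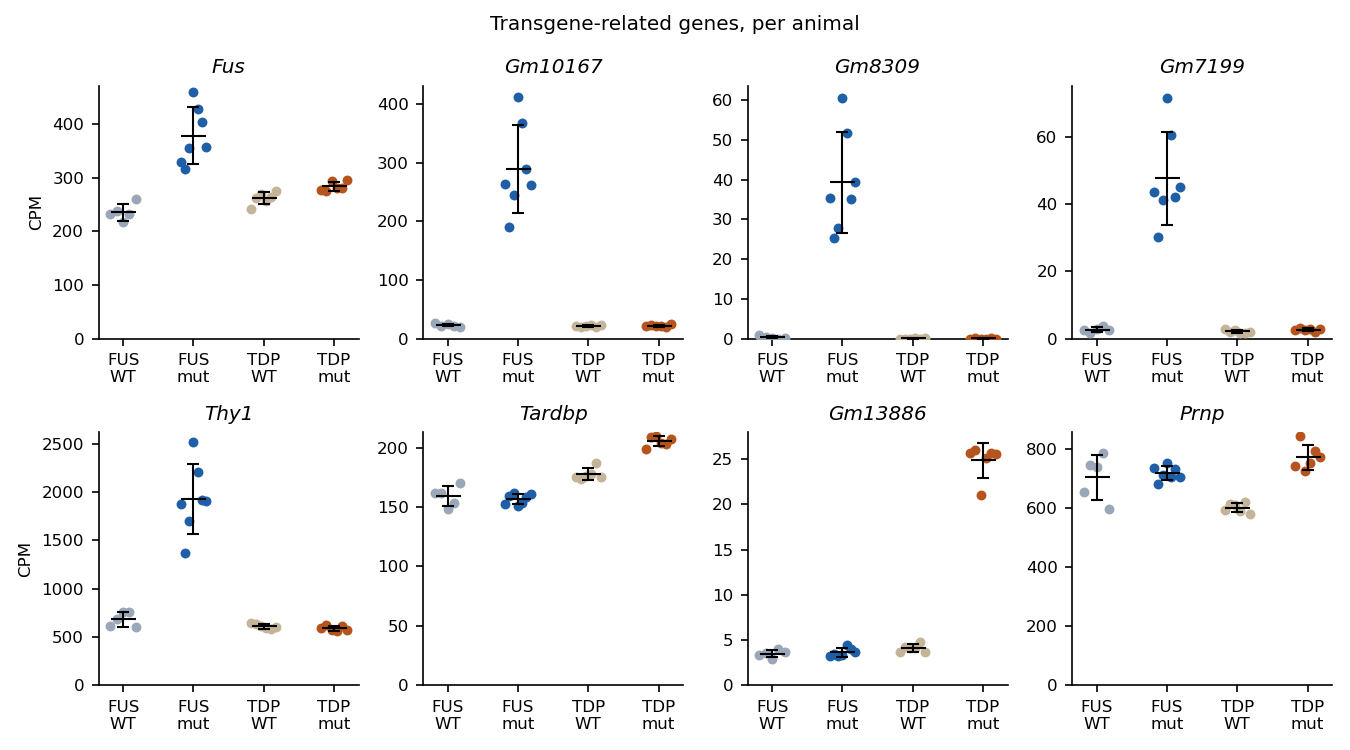
CPM (y axis) of 8 genes in each of the 24 mice, normalised over all 24 libraries, by line and genotype (WT, wild type; mut, mutant); points are mice, and bars are the mean with SD. Fus, Thy1 and the Fus pseudogenes stand apart in the FUS mutants, with Thy1 2.83-fold higher than in their wild types, and Gm13886 stands apart in the TDP mutants, 6.14-fold higher than in theirs.

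By gene group, the list of transgene and promoter genes (Fus, Tardbp, Prnp and Thy1) rose in FUS mutants, with 2 of its 4 members past threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 1.26e-15, and 0.000282 with an estimated correlation). Another 14 of the 42 lists passed at the preset correlation, and none of these held with an estimated correlation (adjusted p from 0.636 to 0.656). Immediate-early genes, which neurons induce on activity, were higher for 17 of 19 members (median log2 0.38, camera adjusted p = 7.99e-06, and 0.636 with an estimated correlation). None of them passed over all genes or adjusted over the list alone. Nptx2 (ENSMUSG00000059991), a secreted synaptic pentraxin, was 75.6 ± 9.25 CPM (SD, n = 7) against 62.2 ± 8.26 CPM (n = 5), with an edgeR adjusted p of 0.846.

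Cortical excitatory neuron genes were higher for 14 of 17 members (median log2 0.14, camera adjusted p = 0.00061, and 0.636 with an estimated correlation). Adjusted over the list alone, 3 were higher and 1 lower, and 0 passed over all genes. Neurod6 (ENSMUSG00000037984), a transcription factor of these neurons, was 75.7 ± 12.8 CPM (SD, n = 7) against 52.1 ± 7.25 CPM (n = 5), with an edgeR adjusted p of 0.522. DESeq2 called it (adjusted p = 0.0214). Among males alone the median of this list was log2 0.02 (camera adjusted p = 0.359). Genes of the meninges, a neighbouring tissue, were lower for 15 of 16 members (median log2 -0.25, camera adjusted p = 0.000676, and 0.644 with an estimated correlation), and adjusted over the list alone 1 was lower. The meninges list no longer passed without mutant 4 (median log2 -0.10). The member, Dcn (ENSMUSG00000019929), a matrix proteoglycan, was 12.4 ± 3.97 CPM (SD, n = 7) against 23.6 ± 8.48 CPM (n = 5), with an edgeR adjusted p of 0.801.

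Oligodendrocyte and myelin genes were higher for 19 of 21 members (median log2 0.20, camera adjusted p = 0.00116, and 0.656 with an estimated correlation), and mitochondrially encoded genes for 7 of 7 (median log2 0.11, camera adjusted p = 0.00505, and 0.636 with an estimated correlation). The myelin list no longer passed without mutant 2 (median log2 0.10) or wild type 2 (median log2 0.07). Lists of homeostatic microglia, astrocytes, layer 5 and corticospinal neurons, glucocorticoid-induced genes, presynaptic genes, voltage-gated ion channels, and cytoskeleton and axonal transport were also higher, with medians of log2 0.05 to 0.08 (camera adjusted p from 0.00226 to 0.02, and 0.636 to 0.656 with an estimated correlation). Lists of interferon-stimulated genes (median log2 -0.09) and of complement and MHC class I (median log2 -0.13) were lower (camera adjusted p = 0.02 and 0.0409, and 0.636 for both with an estimated correlation). None of these members passed over all genes or adjusted over the list alone. Each of these lists was lost without some library, such as microglia without mutant 1 (median log2 0.02), mutant 3 (0.06), wild type 4 (0.07) or wild type 5 (0.07), and astrocytes without mutant 1 (0.01) or wild type 4 (-0.01). Layer 5 neurons were lost without mutant 4 (0.05), wild type 3 (0.04) or wild type 5 (0.05), glucocorticoid-induced genes without mutant 2 (0.04), wild type 1 (0.05) or wild type 4 (0.01), presynaptic genes without wild type 1 (0.05) or wild type 5 (0.05), ion channels without mutant 4 (0.06) or wild type 4 (0.01), and cytoskeleton without wild type 5 (0.06). The interferon list was lost without mutant 1 (-0.07), mutant 6 (-0.08), wild type 1 (-0.10) or wild type 5 (-0.03), and the complement list without mutant 4 (-0.08), mutant 5 (-0.13), mutant 6 (-0.12), wild type 2 (-0.10) or wild type 3 (-0.12). Among males alone the lists of layer 5 neurons, interferon-stimulated genes, complement, presynaptic genes, ion channels and cytoskeleton no longer passed (camera adjusted p from 0.0614 to 0.598). By exact permutation of list scores over the 12 mice, the lowest p was 0.00126 (0.0530 adjusted over the 42 lists), for the transgene list. That is the smallest p the 792 assignments can give, so a single list could not pass this test after adjustment.

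The remaining 27 lists did not pass in FUS mutants (camera adjusted p from 0.0506 to 0.909). They were those of sex-linked genes, RNA-binding proteins, ALS and FTD genes, disease-associated microglia, reactive astrocytes, oligodendrocyte precursors, upper-layer, layer 6 and inhibitory neurons, endothelial cells, striatum, thalamus, hippocampus, choroid plexus, red blood cells, the integrated stress response, heat shock proteins, the circadian clock, the p53 response, postsynaptic genes, GABA-A receptors, long neuronal genes, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, autophagy and lysosome, and nuclear-retained RNAs. Fus was the 1 member of the RNA-binding and of the ALS and FTD lists past threshold.

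The comparison of TDP mutants with wild-type littermates asked the same of the A315T TARDBP transgene. Counts on Tardbp and Prnp rose modestly, and 4 genes with low wild-type counts rose many-fold. Tardbp (ENSMUSG00000041459, chromosome 4, 148612382 to 148627019) was 209 ± 4.44 CPM (SD, n = 6) in mutants and 180.0 ± 5.10 CPM (n = 6) in wild types, a 1.16-fold rise (log2 0.22, SE 0.03, edgeR adjusted p = 0.00734). Prnp (ENSMUSG00000079037, chromosome 2, 131909928 to 131938429), whose promoter drives the transgene, was 788 ± 40.8 CPM against 610.4 ± 15.1 CPM (n = 6 and 6), a 1.29-fold rise (log2 0.37, SE 0.04, edgeR adjusted p = 0.000508). For both, 6 of 6 mutants lay above every wild type. Tardbp overlaps Masp2 and Prnp overlaps Prn, so the gene of origin of some of their reads is uncertain. With the striatal list score as a covariate, chosen after seeing the data, Tardbp was no longer past threshold (log2 0.19, edgeR adjusted p = 0.0570). Thy1 was 599 ± 23.5 CPM against 618 ± 26.1 CPM and Fus 290.2 ± 9.03 CPM against 265 ± 10.4 CPM (edgeR adjusted p = 0.749 and 0.237). DESeq2 called Fus (adjusted p = 0.0488).

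Olfr914 (ENSMUSG00000047050, chromosome 9, 38605102 to 38610978), an olfactory receptor gene, had 859 counts over the 6 mutants and 1 over the 6 wild types, at 8.19 ± 1.33 CPM (SD, n = 6) in mutants. The ratio of levels was 929, with a 95% counting interval of 166 to 36733.5 (edgeR adjusted p = 4.16e-10). Lamr1-ps1 (ENSMUSG00000081229, chromosome 2, 131904086 to 131904959), a processed pseudogene that ends 4969 bases before the start of Prnp, had 261 counts in mutants and 0 in wild types. It was at 2.49 ± 0.381 CPM (n = 6) in mutants, 94.1-fold higher with a floor of 3 counts over the group (edgeR adjusted p = 1.41e-05). The lower limit of its 95% counting interval was 76.0-fold. Gm13886 and Gm49745 were chosen after their values were seen. Gm13886 (ENSMUSG00000083856, chromosome 2, 104820179 to 104821361), a pseudogene with 93.9% identity to Tardbp over 1202 bases, was 25.4 ± 1.88 CPM against 4.15 ± 0.419 CPM (n = 6 and 6), 6.14-fold higher (edgeR adjusted p = 9.66e-11). Gm49745 (ENSMUSG00000116604, chromosome 16, 20566358 to 20568508), a non-coding RNA, was 3.39 ± 0.835 CPM against 0.400 ± 0.138 CPM (n = 6 and 6), 8.55-fold higher (edgeR adjusted p = 1.41e-05). For these 4 genes, 6 of 6 mutants lay above every wild type. Olfr914 shares near-identical stretches with 2 other genes, Gm49745 with 14 and Gm13886 with 1. The gene of origin of reads on these is uncertain, and the source of the rise on Olfr914 was not tested.

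Of 18018 genes tested with edgeR, 51 passed, 26 higher and 25 lower, and 35 of them changed by less than 0.5 on the log2 scale. An unadjusted p under 0.05 was found for 1799 genes, 881 higher and 918 lower, where chance gives 900.9. Among genes with larger rises, Hnrnpm (ENSMUSG00000059208), a splicing regulator, was 143 ± 3.45 CPM (SD, n = 6) against 108 ± 6.82 CPM (n = 6; log2 0.40, edgeR adjusted p = 0.000508). Lats1 (ENSMUSG00000040021), a kinase of the Hippo pathway, was 79.6 ± 4.45 CPM against 61.6 ± 4.76 CPM (n = 6 and 6; log2 0.37, edgeR adjusted p = 0.00797). Col2a1 (ENSMUSG00000022483), type II collagen, rose by log2 0.86, from 1.47 ± 0.163 to 2.65 ± 0.205 CPM, and P3h3 (ENSMUSG00000023191), of the collagen prolyl 3-hydroxylase family, by log2 0.41, from 23.8 ± 2.44 to 31.7 ± 1.41 CPM. Mocos (ENSMUSG00000039616), molybdenum cofactor sulfurase, rose by log2 0.74, and Dnhd1 (ENSMUSG00000030882) and Zcwpw1 (ENSMUSG00000037108) each by log2 0.39. The edgeR adjusted p of these 5 genes ran from 0.00288 to 0.04.

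Among genes that fell, Rpl15 (ENSMUSG00000012405), Rpl23 (ENSMUSG00000071415) and Rps15a (ENSMUSG00000008683), which encode ribosomal proteins, fell by 0.57, 0.43 and 0.40 on the log2 scale (edgeR adjusted p = 0.000515, 0.00558 and 0.00246). Rpl15 was 27.2 ± 2.42 CPM (SD, n = 6) in mutants and 40.6 ± 2.79 CPM (n = 6) in wild types. Ap2m1 (ENSMUSG00000022841, chromosome 16, 20535478 to 20544909), a subunit of the clathrin adaptor complex, was 29.1 ± 1.54 CPM against 40.3 ± 2.47 CPM (n = 6 and 6; log2 -0.47, edgeR adjusted p = 0.000508). The pseudogenes Gm13509 (ENSMUSG00000081272) and AC111023.1 (ENSMUSG00000117935), with 99.7% and 97.3% identity to Ap2m1 and chosen after their values were seen, fell by 0.58 and 0.56 on the log2 scale. Near-identical copies exist for these 3 ribosomal protein genes too, so the gene of origin of their reads is uncertain.

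Trank1 (ENSMUSG00000062296) was 539.8 ± 42.4 CPM (SD, n = 6) against 712 ± 40.8 CPM (n = 6; log2 -0.40, edgeR adjusted p = 0.00471). Clns1a (ENSMUSG00000025439), a chaperone of spliceosomal particle assembly, was 34.7 ± 1.20 CPM against 45.3 ± 3.08 CPM (n = 6 and 6; log2 -0.38, edgeR adjusted p = 0.00249). Chid1 (ENSMUSG00000025512) fell by 0.39 on the log2 scale, Slc9a9 (ENSMUSG00000031129), an endosomal sodium-proton exchanger, by 0.43, Rmnd1 (ENSMUSG00000019763), of mitochondrial translation, by 0.36, and Arfgef2 (ENSMUSG00000074582), a regulator of vesicle traffic, by 0.33 (edgeR adjusted p from 0.00362 to 0.042). Vapb (ENSMUSG00000054455), an endoplasmic reticulum protein mutated in a form of ALS, was 139 ± 5.16 CPM against 161 ± 3.87 CPM (n = 6 and 6; log2 -0.21, edgeR adjusted p = 0.0222). Hspa4 (ENSMUSG00000020361), a co-chaperone of the HSP70 system, was 251 ± 14.4 CPM against 301 ± 16.5 CPM (n = 6 and 6; log2 -0.26, edgeR adjusted p = 0.0386). Of the 51 genes, 40 overlap another annotated gene or share near-identical sequence with one, among them Hnrnpm, Lats1, P3h3, Chid1, Clns1a, Dnhd1, Zcwpw1, Slc9a9 and Rmnd1. Col2a1, Trank1, Vapb, Hspa4 and Arfgef2 do neither.

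The number of genes moved with the libraries and the test. It was 25 without mutant 4, 29 without mutant 2 or mutant 5, 32 without wild type 1, 31 without wild type 2 and 33 without wild type 3, and 24 of the 51 genes passed with any 1 library left out. Those 24 included Tardbp, Prnp, Olfr914, Lamr1-ps1, Hnrnpm, Lats1, Col2a1, P3h3, Trank1, Clns1a, Chid1, Ap2m1 and the 3 ribosomal protein genes. Mocos, Dnhd1, Zcwpw1, Slc9a9, Rmnd1, Arfgef2, Vapb and Hspa4 were each lost in 7 to 11 of the 12 fits with a library left out. A fit of all 24 libraries shared 37 of the 51 genes and ended the calls on Col2a1 (edgeR adjusted p = 0.171), P3h3 (0.0968), Mocos (0.211), Dnhd1 (0.234), Slc9a9 (0.115) and Rmnd1 (0.0617). DESeq2 called 145 genes, 72 higher and 73 lower, with all 51 among them. With the striatal list score as a covariate 31 genes passed, 26 of them shared with the 51. Besides Tardbp, this covariate ended the calls on Mocos, Dnhd1, Zcwpw1, Lats1, Slc9a9, Rmnd1, Arfgef2 and Hspa4 (edgeR adjusted p from 0.0567 to 0.242).

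**Figure D2:**
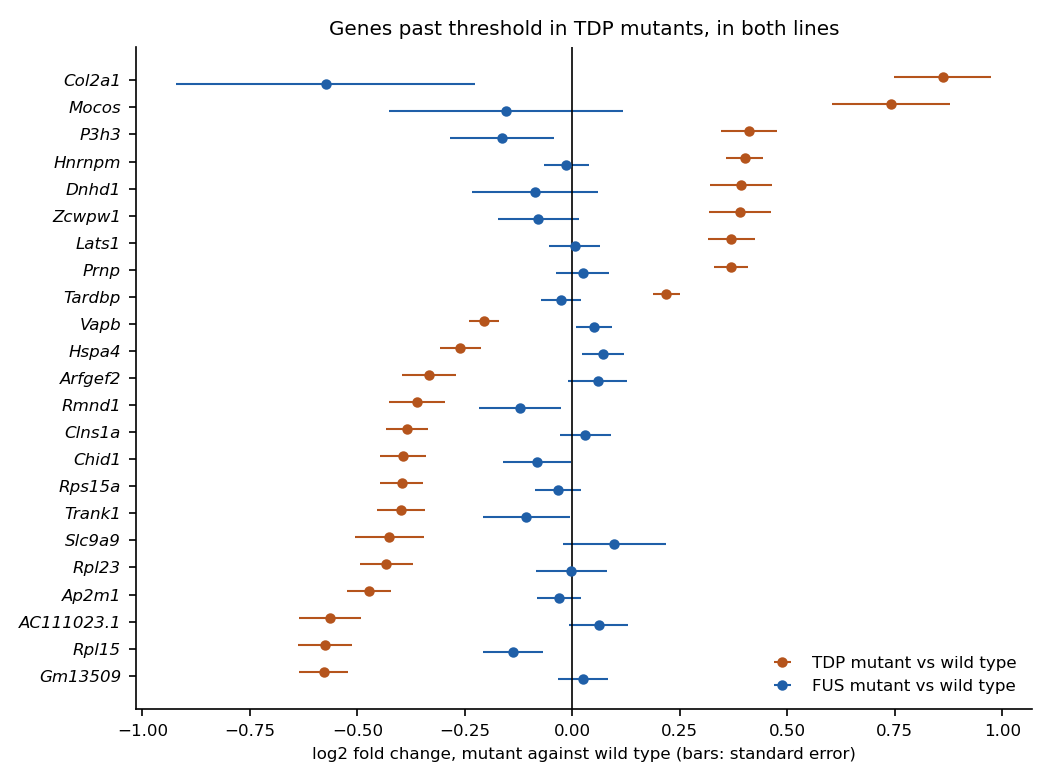
Log2 fold change of mutant against wild type (x axis) for named genes past threshold in the TDP line, with those that rose more than 6-fold left out, in the TDP line (n = 6 and 6) and in the FUS line (n = 7 and 5); points are edgeR estimates, and bars are SE. Values in the TDP line run from log2 -0.58 for Gm13509 to 0.86 for Col2a1, and none of these genes passed in the FUS line.

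By gene group, the list of transgene and promoter genes rose in TDP mutants, with 2 of 4 members past threshold over all genes and 3 adjusted over the list alone, Fus being the third (camera adjusted p = 3.23e-07, and 0.0098 with an estimated correlation). Another 12 lists passed at the preset correlation, and none of these held with an estimated correlation (adjusted p from 0.510 to 0.691). Oligodendrocyte and myelin genes were lower for 21 of 21 members (median log2 -0.33, camera adjusted p = 3.19e-13, and 0.525 with an estimated correlation), and 10 were lower adjusted over the list alone, against 0 over all genes. Car2 (ENSMUSG00000027562), a carbonic anhydrase of oligodendrocytes, was 117 ± 8.27 CPM (SD, n = 6) against 138 ± 6.23 CPM (n = 6), with an edgeR adjusted p of 0.0732, and DESeq2 called it (adjusted p = 0.00292). With the striatal list score as a covariate the median of the myelin list was log2 -0.17 (camera adjusted p = 1.19e-05).

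Homeostatic microglia genes were lower for 20 of 20 members (median log2 -0.16, camera adjusted p = 1.51e-08, and 0.510 with an estimated correlation), and 6 were lower adjusted over the list alone, against 0 over all genes. Fcrls (ENSMUSG00000015852), a microglial receptor, was 25.3 ± 1.35 CPM (SD, n = 6) against 28.8 ± 1.45 CPM (n = 6), with an edgeR adjusted p of 0.199. Mitochondrially encoded genes were lower for 7 of 7 members (median log2 -0.19, camera adjusted p = 1.88e-07, and 0.510 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. Of these, mt-Nd6 (ENSMUSG00000064368), a subunit of respiratory complex I, was 1884 ± 124 CPM (SD, n = 6) against 2228 ± 203 CPM (n = 6), with an edgeR adjusted p of 0.199. Nuclear-encoded oxidative phosphorylation genes were lower for 29 of 34 members (median log2 -0.06, camera adjusted p = 0.000216, and 0.635 with an estimated correlation). Cytosolic ribosomal protein genes were lower for 35 of 41 members (median log2 -0.07, camera adjusted p = 1.75e-05, and 0.635 with an estimated correlation). Rpl15 and Rpl23 passed over all genes, and 3 passed adjusted over the list alone. Counts on this list were low, with a list score (mean log2 CPM) of 3.26 in mutants and 3.34 in wild types. Near-identical copies were searched only for genes past threshold, so the origin of reads on the other members is uncertain.

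Striatal genes were lower for 15 of 15 members in TDP mutants (median log2 -0.81, camera adjusted p = 3.23e-07, and 0.635 with an estimated correlation). Tac1 (ENSMUSG00000061762), a neuropeptide precursor, was 16.5 ± 13.97 CPM (SD, n = 6) against 32.7 ± 18.7 CPM (n = 6), with an edgeR adjusted p of 0.509. Meninges genes were higher for 16 of 16 members (median log2 0.29, camera adjusted p = 1.48e-06, and 0.635 with an estimated correlation), and red blood cell genes were lower for 5 of 5 (median log2 -0.40, camera adjusted p = 0.0276, and 0.635 with an estimated correlation). Immediate-early genes were higher for 19 of 19 members (median log2 0.32, camera adjusted p = 0.000355, and 0.635 with an estimated correlation). With the striatal list score as a covariate this median was log2 0.05 (camera adjusted p = 0.499), and the red blood cell list no longer passed either (camera adjusted p = 0.415). The red blood cell list was also lost without mutant 2 (median log2 -0.30), mutant 4 (-0.33), mutant 6 (-0.30), wild type 1 (-0.24) or wild type 2 (-0.36). None of the members of these 4 lists passed over all genes or adjusted over the list alone.

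**Figure D3:**
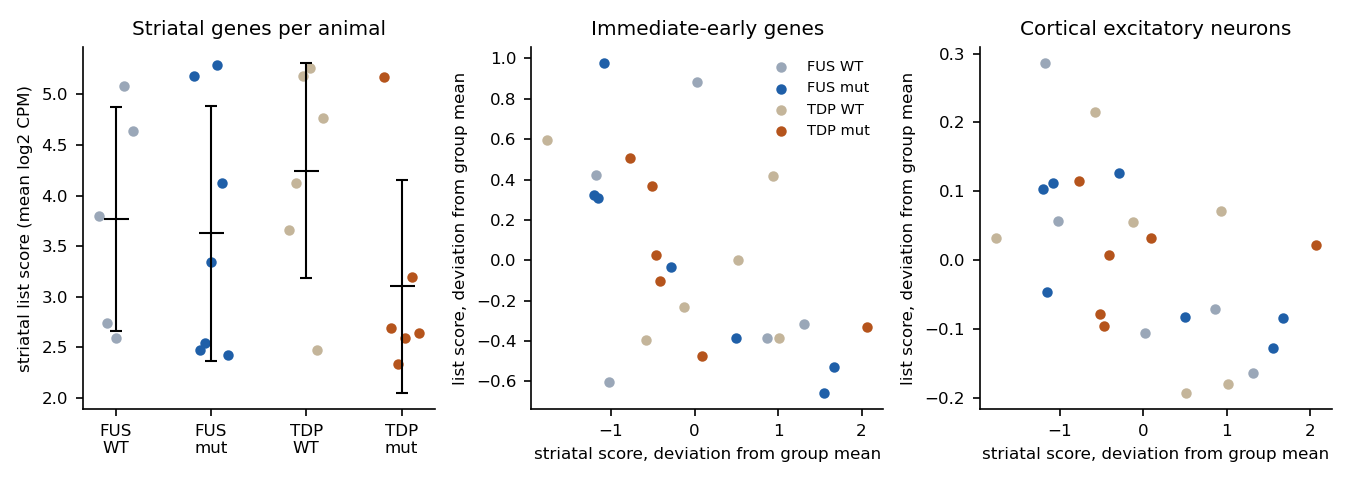
Left, striatal list score (mean log2 CPM) of each of the 24 mice by line and genotype, with bars at the mean with SD; middle and right, scores of immediate-early and of cortical excitatory neuron genes (y axes) against the striatal score (x axes), each as deviations from the 4 group means. Over the 24 mice, r was -0.568 for immediate-early genes and -0.547 for excitatory neuron genes (permutation adjusted p = 0.018 for both).

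Reactive astrocyte genes were higher for 19 of 21 members (median log2 0.13, camera adjusted p = 0.00687, and 0.528 with an estimated correlation). Adjusted over the list alone 2 passed, among them Vim (ENSMUSG00000026728), an intermediate filament gene, at 33.4 ± 2.76 CPM (SD, n = 6) against 28.2 ± 1.82 CPM (n = 6), and 0 passed over all genes. Astrocyte genes were lower for 15 of 19 members (median log2 -0.07, camera adjusted p = 0.00658, and 0.635 with an estimated correlation), with 1 lower adjusted over the list alone. Its member Aldoc (ENSMUSG00000017390), a glycolytic enzyme gene chosen in this line after its values were seen, fell into separate levels. It was at 13.7 to 18.8 CPM in mutants 1, 2, 4 and 6 and wild type 4, and at 285 to 324 CPM in mutant 3 and wild types 1, 2 and 3. Mutant 5 and wild types 5 and 6 were at 570 to 681 CPM (edgeR adjusted p = 0.735 for mutants against wild types). All mice of the FUS line were at 583 to 857 CPM. The source of these levels, which were spread unevenly over the TDP genotypes, was not tested. Without Aldoc the astrocyte list had a median of log2 -0.07 (camera adjusted p = 0.0129, and 0.635 with an estimated correlation). Endothelial and pericyte genes were higher for 17 of 21 members (median log2 0.09, camera adjusted p = 0.0276, and 0.691 with an estimated correlation), with 0 past over all genes or adjusted over the list alone. The astrocyte list was lost without mutant 1 (median log2 -0.07) or wild type 5 (-0.05), and the endothelial list without mutant 1 (0.08), mutant 3 (0.04), mutant 5 (0.07), wild type 5 (0.01) or wild type 6 (0.07). With the striatal list score as a covariate the reactive astrocyte list no longer passed (median log2 0.11, camera adjusted p = 0.0561). By exact permutation of list scores over the 12 mice, the lowest p was 0.00216 (0.0909 adjusted over the 42 lists), for the transgene list. That is the smallest two-sided p the 924 assignments can give, so a single list could not pass this test after adjustment.

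The remaining 29 lists did not pass in TDP mutants (camera adjusted p from 0.0509 to 0.879). Besides the lists that did not pass in the FUS line either, these were the lists of excitatory and layer 5 neurons, interferon-stimulated genes, complement and MHC class I, glucocorticoid-induced genes, presynaptic genes, ion channels, and cytoskeleton and axonal transport. In the ALS and FTD list Tardbp rose and Vapb fell, and 25 of 27 members did not pass over all genes. In the list of RNA-binding proteins 1 of 23 members passed over all genes (Tardbp) and 2 adjusted over the list alone (Fus and Tardbp). In the heat shock list 1 of 16 passed over all genes (Hspa4) and 2 adjusted over the list alone. Adjusted over the list alone, 3 autophagy and lysosome genes and 2 of layer 5 neurons passed, in both directions, against 0 over all genes.

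**Figure D4:**
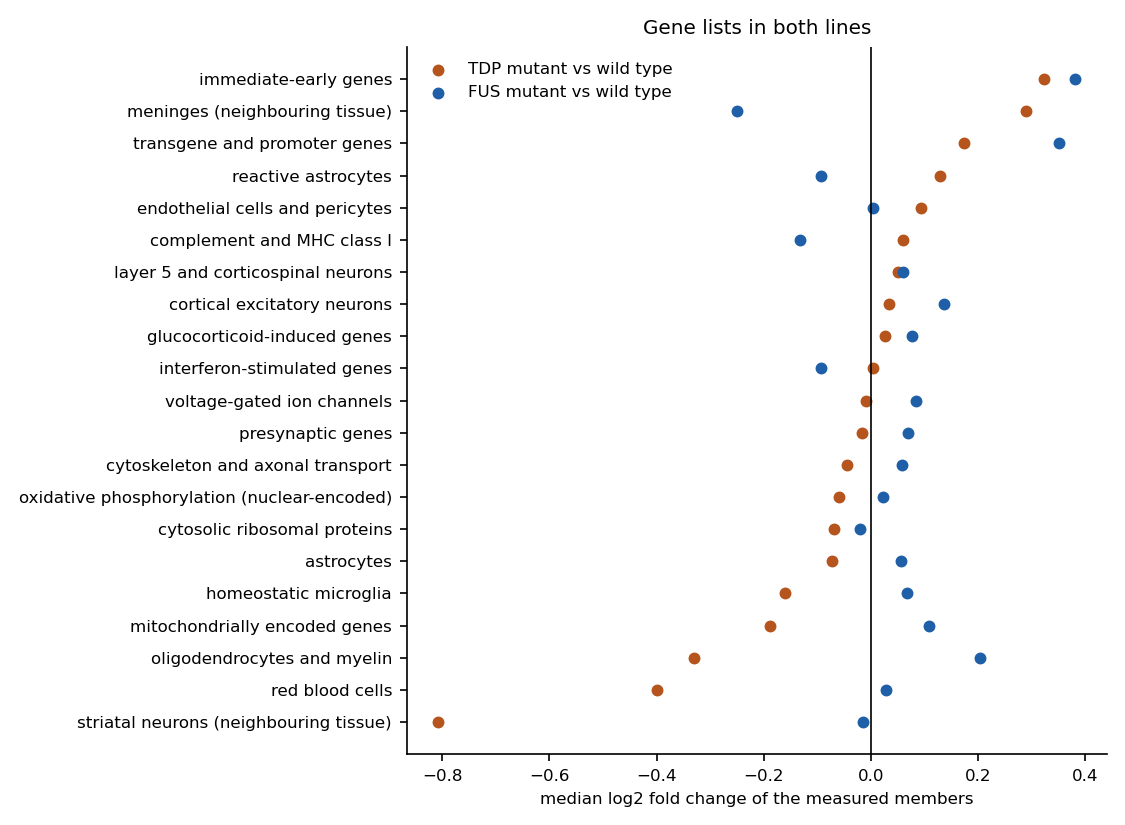
Median log2 fold change of mutant against wild type over the measured members (x axis) of each gene list that passed camera at the preset correlation in at least 1 line, for the FUS line (n = 7 and 5 mice) and the TDP line (n = 6 and 6). Medians for myelin genes were log2 0.20 in the FUS line and -0.33 in the TDP line, and those for immediate-early genes 0.38 and 0.32; apart from the transgene list, these calls were lost with an estimated correlation (adjusted p from 0.510 to 0.691).

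The difference of mutant effects, FUS minus TDP, asked which genes responded differently in the lines; ages differed between the lines, so the effects of line and age are not separable. Of 18949 genes tested with edgeR, 21 passed, 12 with a higher and 9 with a lower effect in the FUS line, and 1703 had an unadjusted p under 0.05. Thy1 (log2 1.54, SE 0.13, edgeR adjusted p = 1.19e-07) and Fus (log2 0.55, SE 0.10, edgeR adjusted p = 0.0191) differed with the rise in FUS mutants. Ap2m1 (log2 0.44), Clns1a (log2 0.41), Vapb (log2 0.26) and Hspa4 (log2 0.33) differed with the fall in TDP mutants (edgeR adjusted p from 0.00427 to 0.0428). Lower effects in the FUS line were found for Hnrnpm (log2 -0.42), Dhx37 (ENSMUSG00000029480, log2 -0.44), an RNA helicase of ribosome assembly, Adam15 (ENSMUSG00000028041, log2 -0.38), a metalloprotease, and Fam83h (ENSMUSG00000046761, log2 -0.83), with edgeR adjusted p from 0.00313 to 0.049. Tardbp (log2 -0.25) and Prnp (log2 -0.35) both had an edgeR adjusted p of 0.0607 and did not pass, and DESeq2 called both (adjusted p = 0.00104 and 0.00311). DESeq2 called 49 genes, and 40 passed without wild type 3 of the FUS line. Males alone gave 9 genes, without Clns1a, Vapb, Hspa4, Hnrnpm, Dhx37, Adam15 or Fam83h (edgeR adjusted p from 0.0689 to 0.391). Thy1, Fus, Ap2m1 and Hnrnpm passed with any 1 library left out, Clns1a did not without TDP wild type 2, and Vapb, Hspa4, Dhx37, Adam15 and Fam83h were each lost in 15 to 21 of the 24 fits. With a replicate block Clns1a, Vapb, Dhx37 and Fam83h did not pass.

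Of the 42 lists, 19 differed between the lines at the preset correlation, 16 with a higher and 3 with a lower effect in the FUS line, and 0 with an estimated correlation (lowest adjusted p = 0.115, for the transgene list). Myelin genes had a higher effect in the FUS line for 20 of 21 members (median log2 0.53, camera adjusted p = 3.52e-11, and 0.434 with an estimated correlation), homeostatic microglia genes for 20 of 20 (median log2 0.24, camera adjusted p = 8.15e-09, and 0.434 with an estimated correlation), and mitochondrially encoded genes for 7 of 7 (median log2 0.29, camera adjusted p = 8.15e-09, and 0.366 with an estimated correlation). Meninges genes had a lower effect for 16 of 16 (median log2 -0.57, camera adjusted p = 3.91e-07, and 0.434 with an estimated correlation). Adjusted over the list alone 1 myelin, 3 microglia and 6 mitochondrially encoded genes passed, against 0 over all genes. Heat shock (median log2 0.10), long neuronal (0.12), GABA-A receptor (0.13), autophagy (0.04) and cholesterol synthesis (0.09) genes also differed (camera adjusted p from 0.00643 to 0.0427, and 0.434 to 0.613 with an estimated correlation). Lists that did not differ had camera adjusted p from 0.0551 to 0.962.

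Across 17706 genes tested in both lines, the effects had Pearson's r = 0.0130 and Spearman's rho = -0.0425, across genes that are not independent replicates. Exact permutation of genotype gave two-sided p = 0.972 over the 924 assignments of the TDP line and p = 0.957 over the 792 assignments of the FUS line. Over these assignments r ran from -0.543 to 0.543 and from -0.431 to 0.423. A moderate shared effect would lie within those ranges, so its absence is not shown. Leaving out 1 library moved r between -0.169 (without TDP mutant 3) and 0.102 (without TDP wild type 3). No gene passed in both lines with edgeR: of genes tested in both, 4 in the FUS line and 22 in the TDP line were higher, with 0 shared (0.00497 expected, Fisher's exact p = 1), and 0 and 25 were lower. DESeq2 called 1 gene higher in both lines and 0 lower. At an unadjusted p under 0.05, 8 genes were higher in both lines (20.2 expected, Fisher's exact p = 0.00253) and 18 lower in both (31.9 expected, Fisher's exact p = 0.00721). In opposite directions, 15 were higher in the FUS line and lower in the TDP line (21.6 expected, Fisher's exact p = 0.178), and 25 the reverse (29.9 expected, Fisher's exact p = 0.391). All 4 counts lay below those that independent draws of genes give. Fisher's test treats genes as independent, which they are not, and mice were not permuted for this overlap. A shortfall of shared genes between the lines is therefore not shown.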

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

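The tests of gene positions, of females, of Gm13886, of Lamr1-ps1 and of the region around Ap2m1 were chosen after the results were seen. The other tests of pseudogenes and of the myelin list were worded for results already called. For these, a bound set beforehand was set before the test and not before the calls.

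Pseudogenes of the transgenes rose in each line. In FUS mutants, 4 of the 4 processed pseudogenes past threshold aligned to a Fus transcript at 80% identity or more over at least 100 bases, as did 4 of the 5 genes past threshold other than Fus, against 1680 of the 18098 tested genes (Fisher's exact p = 0.000343 for the 4 of 5). This bound alone does not mark copies of Fus: Ap2m1, Padi2 and Gm48267 met it too, over 178 to 186 bases. The alignments of Gm10167, Gm7199 and Gm8309 ran over 1492 to 1570 bases. Gm10167 (log2 0.06) and Gm7199 (log2 0.34) did not pass in TDP mutants. In TDP mutants, 1 of the 2 pseudogenes with a log2 rise over 1 aligned to Tardbp, Gm13886, at 93.9% identity, so Tardbp copies do not account for Lamr1-ps1. Lamr1-ps1 lies 4969 bases from Prnp and had 0 counts in the 18 other mice, and Prnp flanking DNA carried by the transgene stays open as its source, since the extent of that DNA was not analysed here. A candidate explanation for the Fus pseudogenes and Gm13886 is that reads of the human transgenes were counted on mouse copies; transcription of the mouse loci themselves was not tested. The same stays open for the rises on Fus and Tardbp. Rises on Thy1 and Prnp were not told apart from reads of any Thy1 or Prnp sequence carried by the transgenes. A rise of the mouse genes themselves is therefore not shown.

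The genes that changed in TDP mutants were not packed in the genome: 4 of 51 lay within 2 Mb of another, against a mean of 6.08 in random draws (share as high 0.828). That argues against 1 inserted or co-inherited segment as the source of most of them. Ap2m1 fell and Gm49745, 21449 bases away, rose, and 4 of 19 other genes within 200 kb of Ap2m1 had an unadjusted p under 0.05 (Fisher's exact p = 0.114). The pseudogene Gm49744 (chromosome 16, 20565577 to 20566028) lies between the 2 and was seen after the results. It was at 0.782 CPM in TDP mutants and 0.0785 CPM in their wild types, and passed for the difference of effects (log2 -3.37, edgeR adjusted p = 0.0428). That call, at low counts, was lost in 19 of the 24 fits with a library left out. An altered stretch of chromosome 16 and a response to the transgene cannot be told apart, since 19 genes are few. The near-identical copies Gm13509 and AC111023.1 fell with Ap2m1, so reads shared with it may account for part of their fall.

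Myelin genes were lower in TDP mutants as a list, with scores of 5.82 ± 0.271 against 6.15 ± 0.175 (SD, n = 6 and 6). Exact permutation over the 12 mice gave p = 0.0368, and 0.258 after adjustment over the 42 lists. The bound set beforehand for this test took no account of the choice of this list among 42, so spread between mice in a shared program stays open. Within groups, myelin and striatal scores had r = 0.305 over the 24 mice (permutation p = 0.146), between the bounds set beforehand, so differing amounts of striatum and white matter in the tissue cannot be told apart from an effect of genotype on myelin. By line, r was 0.542 in the TDP line and 0.170 in the FUS line (n = 12 each). With the striatal list score as a covariate the median of the list was log2 -0.17 in place of -0.33.

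Genotype labels were reassigned within a line in 100 splits, the real one included. For genes past threshold, 1 split in the FUS line (real 6, highest other 5), 2 in the TDP line (real 51, highest other 190) and 2 for the difference of effects (real 21, highest other 52) gave as many. These shares lay under the bound set beforehand, so counts as large were rare under reassigned labels. In the TDP line and for the difference of effects, a reassigned split gave more genes than the real one, so chance is not excluded for those counts. The TDP split with 190 genes points to a structure of the samples: its groups differed by -1.44 in striatal score, against -1.14 for the real groups. Striatal score alone does not account for it, since splits with differences of -1.68, -1.70, 1.71 and -1.51 gave 0, 0, 2 and 13 genes with edgeR. The hippocampal list score was 1.51 to 1.61 in replicates 1 and 3 of both TDP genotypes and 1.93 to 2.44 in the other TDP mice. Pairs among TDP mutants 2, 4, 5 and 6 had a chi-square per degree of freedom of 3.45 to 5.89, and pairs with mutant 1 or 3 had 11.2 to 15.2. Mutants 1 and 3 were also unlike each other, at 11.2. The wild types did not show this division. Their pairs among 2, 4, 5 and 6 had 4.62 to 15.4, and those with wild type 1 or 3 had 7.03 to 17.0. Whether the grouping by hippocampal score, seen after the results, accounts for the split was not tested. For lists past threshold, 29 splits in the FUS line (real 15, highest other 23) and 24 in the TDP line (real 13, highest other 23) gave as many, so chance cannot be excluded. For the difference of effects 2 splits did (real 19, highest other 19), a share under the bound set beforehand. Another split still reached 19 lists, the median of the others was 10, and 0 lists passed with an estimated correlation. Chance is therefore not excluded for these lists either. With a Y-linked covariate 6 genes passed in the FUS line, no more than without it. That argues only against a sex difference alike in both genotypes hiding changed genes. Males alone gave 5, but 5 mutants and 3 wild types leave less power, so this count cannot show whether females hid changed genes.

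A sample lay far from the others of its group in 13 of 212 groups, where chance gives about 1 in 20. Each value is the gap to the nearest sample over the range of the group. In TDP mutants, mutant 3 was low for the library total (0.670) and Gm13886 (0.845), and mutant 1 was high for the striatal score (0.697) and Tac1 (0.752). In TDP wild types, wild type 5 was high for Tardbp (0.692) and low for Rmnd1 (0.664), wild type 1 was low for Chid1 (0.632), and wild type 4 was low for Aldoc (0.776), as were 4 TDP mutants. In the FUS line, mutant 4 was low for the meninges score (0.569), mutant 1 high for Clns1a (0.608) and wild type 4 low for Arfgef2 (0.809). Olfr914 had counts in 1 wild type of each line, FUS wild type 2 and TDP wild type 5 (ratio 1 for both).

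Effects differed between the lines (FUS minus TDP, tested as an interaction, log2) for Fus (0.55), Thy1 (1.54), Gm10167 (3.58), Gm7199 (3.83), Gm13886 (-2.57), Gm49745 (-2.99), Hnrnpm (-0.42), Ap2m1 (0.44), Gm13509 (0.60), AC111023.1 (0.62), Rps15a (0.36), Clns1a (0.41), Vapb (0.26), Hspa4 (0.33), Dhx37 (-0.44), Adam15 (-0.38) and Fam83h (-0.83). Of the 19 lists whose effect differed at the preset correlation, the 14 that also passed within a line had medians as follows: transgene (0.15), microglia (0.24), astrocytes (0.16), myelin (0.53), meninges (-0.57), presynaptic (0.10), ion channels (0.0684), cytoskeleton (0.11), mitochondrially encoded (0.29), reactive astrocytes (-0.23), endothelial (-0.10), striatal (0.86), oxidative phosphorylation (0.0836) and ribosomal proteins (0.0588). None of these lists passed with an estimated correlation (lowest adjusted p = 0.115).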

How the results depend on the processing

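Males alone, an adjusted p under 0.1, the striatal list score as a covariate and the astrocyte list without Aldoc were chosen after seeing the data. RLE scaling, a filter of mean CPM of at least 1, no filter on low counts, a replicate block and, within each line, a fit of all 24 libraries gave 4 to 6 genes past threshold for FUS, 45 to 62 for TDP and 14 to 26 for the difference of effects, all within 1.5-fold. Of the 51 TDP genes, no filter shared 37, the fit of all 24 libraries 37 and the replicate block 40. No filter ended the TDP calls on Dnhd1, Zcwpw1 and Vapb (adjusted p from 0.0531 to 0.0904), the fit of all 24 those on Col2a1, Mocos, P3h3, Dnhd1, Slc9a9 and Rmnd1 (0.0617 to 0.234), and the replicate block those on Zcwpw1, Slc9a9 and Rmnd1 (0.0535 to 0.101). With the replicate block the FUS calls on Fus (log2 0.66, adjusted p = 0.135) and Gm47721 (log2 3.70, adjusted p = 0.124) were lost. For the difference of effects, no filter ended the calls on Vapb, Hspa4, Dhx37, Adam15 and Fam83h (0.126 to 0.205), the replicate block those on Clns1a, Vapb, Dhx37 and Fam83h (0.0771 to 0.0965), and the striatal and the Y-linked covariate those on Dhx37, Adam15 and Fam83h (0.0558 to 0.0867). DESeq2 gave 19 genes for FUS (13 higher, 6 lower), 145 for TDP (72 and 73) and 49 for the difference of effects (25 and 24), and an overlap of 1 higher gene. An adjusted p under 0.1 gave 105 genes for TDP (56 and 49) and 37 for the difference of effects (19 lower), by its construction. The striatal covariate gave 31 for TDP (14 higher), a striatal list median of log2 0.0311 there by its construction, and 5 lower for the difference of effects. For that difference, 5 were lower with no filter and 5 with the Y-linked covariate, which was not run for TDP, where all mice were male. Males alone, with fewer mice, gave 9 (7 and 2). With an estimated correlation 1 list passed for FUS, 1 for TDP and 0 for the difference of effects. Leaving out each library gave 0 to 1 lower genes for FUS, 25 to 52 genes for TDP (13 to 27 higher, 12 to 28 lower; 25 without mutant 4) and 14 to 40 for the difference of effects (5 to 26 lower; 40 without FUS wild type 3). Lists past threshold then numbered 12 to 22 for FUS, 12 to 17 for TDP and 14 to 22 for the difference of effects. The effects of Tardbp and Prnp in FUS, past no threshold, ran from -0.0548 to 0.00208 and from -0.0271 to 0.0666, with Tardbp at 0.0101 in males. The correlation of effects ran from -0.169 without TDP mutant 3 to 0.102 without TDP wild type 3. Beyond these constructions the cause was not tested. Simulated data had the depth and group sizes of these libraries, with genes drawn independently. There, a 1.5-fold change planted in genes with a mean of at least 1 CPM was called for 65.3% in the FUS design and 74.7% in the TDP design.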

Other observations

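The relations of the striatal score to other lists were chosen after the results were seen. Mice with higher striatal expression had lower expression of immediate-early and of cortical excitatory neuron genes. As deviations from the 4 group means over the 24 mice, the striatal score had r = -0.568 with the score of immediate-early genes (rho = -0.546) and r = -0.547 with that of excitatory neuron genes (rho = -0.602; permutation adjusted p = 0.018 for both r, over 6 relations). Without the 2 mice farthest out, r was -0.524 and -0.618. In the FUS line r was -0.625 and -0.757, and in the TDP line -0.483 and -0.277. The other 4 relations, with myelin, microglia, meninges and mitochondrially encoded genes, had permutation adjusted p of 0.157 or higher.

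Among FUS mutants, counts on Fus, Thy1 and Gm10167 were highest in mutant 4, a female, at 460, 2519 and 411 CPM (normalised over all 24 libraries), and next highest in mutant 5, the other female, at 429, 2204 and 367 CPM. The highest of the 5 males, mutant 6, was at 405, 1918 and 289 CPM. They were lowest in mutant 2, at 316, 1370 and 190 CPM.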
